A study of Drosophila melanogaster with 6 samples.

How the data were processed

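Messenger RNA of fly heads was measured by paired-end sequencing (150 bp reads) of 6 libraries, 3 of TubGS flies with the GLAD construct and 3 with the GFP construct, taken on day 7 after RU486 induction. The labels call the tissue a head, and per the labels' protocols total RNA came from 100 brains per sample. Libraries were made with a NEBNext Ultra kit and sequenced on an Illumina instrument, per the labels' protocols. Nothing in the labels says whether replicates came from separate crosses or cultures of flies, so p-values measure only the spread between these samples, which may be technical.

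The authors deposited a single table of FPKM values (fragments normalised to gene length and library size), with 15886 rows. TopHat and the builds BDGP6 and dm6 are named in the submitters' processing notes, without versions. The counting tool, its strand setting, its handling of reads that match several places and the annotation are not given in the sources used here, so overlapping or antisense genes and close copies cannot be separated with certainty. The table held 15682 FlyBase gene IDs, of which 15002 matched a symbol and a place in the Ensembl release 115 annotation of BDGP6 and 680 did not, and 204 further rows for transcripts outside the reference. Coordinates are those of that annotation.

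Low FPKM values multiplied by exon length fell near whole multiples of the same amount within each library, which gave library totals of 22.1 to 29.5 M fragments. With exon lengths from the release 115 annotation, 47.8% to 48.4% of the values worth up to 200 reads were whole within 0.02 reads, where chance gives 4%. The reads recovered in this way sum to 26.6 to 35.4 M, more than the total in every library, so the lengths, the totals or both are inexact, and they served only for a check with voom. Depth sets a step of 0.0169 to 0.0227 FPKM per read at a length of 2000 bp, so values of a few hundredths FPKM rest on single reads, and a gene listed at 0 had no read counted.

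The values were tested as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, without further scaling of the deposited FPKM values. Genes with a mean FPKM of at least 1 entered, and lmFit and eBayes with a mean-variance trend were followed by Benjamini-Hochberg adjustment, two-sided, at a threshold of 0.05. Fold changes are RNAi-GLAD minus RNAi-Ctrl on the log2(FPKM + 1) scale, which understates changes of genes with low values. The main comparison used all 6 libraries as labelled and no replicate block. Gene lists (41, of which 40 had at least 5 tested members) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them to other genes.

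The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes up to 12 genes per direction with the largest absolute fold change among genes under the threshold whose groups do not overlap, or else the 5 smallest p per direction, and up to 4 members of each list with the smallest p. A comparison of the 4 libraries numbered 1 and 2 was added after the values were seen, with the same rule and tests. In that comparison CecA1, CecA2, Trxr1, Sod1 and prtp, and the clock, yolk, heat shock, testis and digestive genes given per library, were named after their values were seen.

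Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, and a mean of 5), median-of-ratios, trimmed-mean and quantile scaling, the trend, array weights, a replicate block, a stricter threshold of 0.01, a minimum log2 fold change of 1, each library left out in turn and, added later, pairs of libraries of the same number left out and voom. The tests were tried on simulated data with 200 changed genes of known size. Noise was drawn independently for each gene and library, so no simulated library stood with the other group. With 6 libraries, 85% of 2-fold and 97% of 4-fold changes were recovered among 9631 genes with 9 false calls, and with 4 libraries 94% and 96% among 9661 genes with 13 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.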

Results

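RNA was sequenced from heads of adult Drosophila melanogaster collected on day 7 after RNA interference had been switched on. The flies carried TubGS, a tubulin-promoter GeneSwitch driver that becomes active throughout the body when the drug RU486 is given in the food. One group expressed an RNA interference construct named GLAD (RNAi-GLAD) and the control group a construct against GFP, a protein that flies do not have (RNAi-Ctrl). Each group had 3 libraries of 100 pooled brains or heads, as the labels name both tissues. The library totals implied by the deposited values were 24.9, 23.9 and 29.5 M fragments for RNAi-Ctrl 1, 2 and 3, and 23.4, 22.5 and 22.1 M fragments for RNAi-GLAD 1, 2 and 3. Reads recovered with the exon lengths of the reference annotation sum to more than these totals in every library (26.6 to 35.4 M), so the lengths, the totals or both are inexact. By these totals a single read in a gene of 2000 bp was worth 0.0169 to 0.0227 FPKM. The labels do not say which gene GLAD stands for, and 0 genes in the name tables carried it as a symbol or synonym. The targeted gene is therefore not reported, and no gene that checks the labels was available.

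The comparison asks which transcripts differ in heads after the GLAD construct is expressed. As labelled, no gene differed between the 2 groups by more than the spread between libraries allows to call. CG13018 had the smallest p, at 7.55 ± 0.251 FPKM in RNAi-Ctrl and 5.29 ± 0.234 FPKM in RNAi-GLAD (SD, n = 3 each), a log2 fold change of -0.44 ± 0.06 (SE). CG6999 (log2 fold change -0.52), FBgn0032906 (-0.30), mt:ATPase6 (-0.31), which encodes a subunit of the mitochondrial ATP synthase, and Cpr67Fb (-0.73) followed among the genes lower in RNAi-GLAD. On the other side stood Rcd5 (0.19), CG3434 (0.29), Dlish (0.34), mir-2490 (0.72) and CG33110 (0.30). None of these 10 genes passed the test: limma gave 0 of 9631 genes under the threshold, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 112 genes where chance gives 481.55, and limma with voom on recovered reads gave 0 genes and 74 at an unadjusted p under 0.05. The groups did not overlap for 385 tested genes (4.0%), and chance gives 10%. For 92.3% of the genes the 95% confidence interval lay within 1 on the log2 scale of 0. In simulated data of this size and spread 85% of 2-fold changes were recovered. No simulated library stood with the other group, as the libraries numbered 3 did here (below). The simulation therefore cannot show that such changes would have been found in these 6 libraries.

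Among the 40 gene lists tested as labelled, 10 passed limma's camera test with a preset correlation, 3 higher and 7 lower in RNAi-GLAD. All 31 proteasome genes had a positive fold change (median 0.10, adjusted p = 1.88e-06), as had 19 of 21 endoplasmic reticulum (ER) chaperone and unfolded protein response genes (median 0.19, adjusted p = 0.00187) and 28 of 33 aminoacyl-tRNA synthetases (median 0.08, adjusted p = 0.0195). All 11 mitochondrially encoded genes had a negative one (median -0.30, adjusted p = 5.88e-09), with a mean level of 4.65 log2 units in RNAi-GLAD 3 and 5.23 to 5.43 in the other 5 libraries. Of the antimicrobial peptides and Bomanins, which insects secrete against infection, 19 of 24 had a negative fold change (median -0.30, adjusted p = 8.87e-06). CecA1 reached 94.1, 31.8 and 9.79 FPKM in RNAi-Ctrl 1, 2 and 3, and 7.16, 20.1 and 2.44 FPKM in RNAi-GLAD 1, 2 and 3. The other lists on the lower side were the synaptic vesicle cycle (20 of 25 negative, adjusted p = 4.74e-04), pan-neuronal genes (14 of 17, adjusted p = 0.00464), testis and male accessory gland markers (17 of 19, adjusted p = 0.0108), cytosolic heat shock proteins (10 of 12, adjusted p = 0.0133) and cytosolic ribosomal proteins (48 of 79, adjusted p = 0.0167). Without RNAi-Ctrl 3 the direction of the heat shock and ribosomal lists turned to higher in RNAi-GLAD (adjusted p = 0.198 and 0.736). Adjusted over the list alone, 0 members of any list passed. None of the 10 calls held with an estimated correlation (smallest adjusted p = 0.833) or with fry (smallest adjusted p = 0.967). The mitochondrially encoded list was the only call of the 10 kept without each library in turn (adjusted p = 0.0276 without RNAi-GLAD 3, the highest of the 6); the antimicrobial peptides, for example, had an adjusted p of 0.319 without RNAi-GLAD 3.

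**Figure D1:**
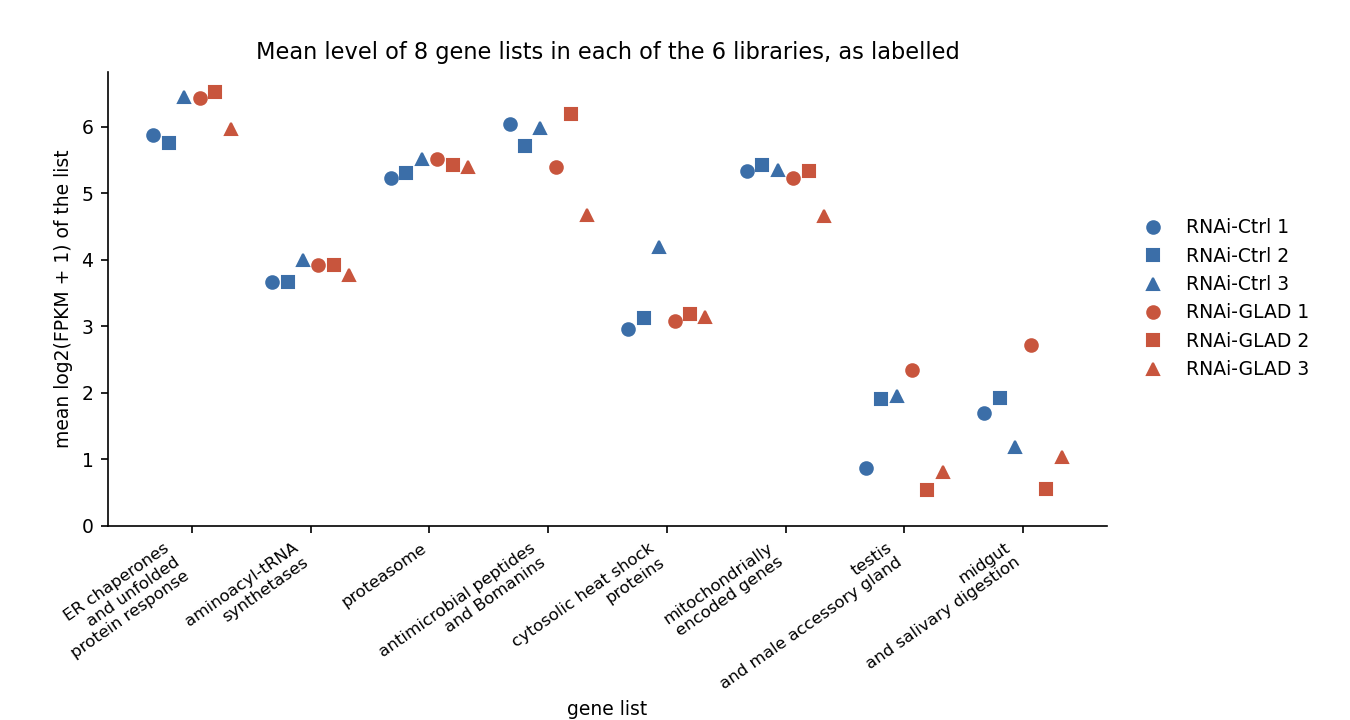
Mean log2(FPKM + 1) of 8 gene lists (y axis) in each library (colour for the labelled group, symbol for the replicate number; 1 point per library). RNAi-GLAD 3 lies lowest for the antimicrobial peptides (4.67) and mitochondrially encoded genes (4.65), RNAi-Ctrl 3 highest for the heat shock proteins (4.19), and testis markers range from 0.535 to 2.34.

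A pair of libraries stood apart from the rest of their groups. The long noncoding RNA lncRNA:CR40469 (X chromosome, 122493 to 122706 in BDGP6) was at 1935 and 2198 FPKM in RNAi-Ctrl 1 and 2 and at 4.20 and 4.77 FPKM in RNAi-GLAD 1 and 2, but at 5.86 FPKM in the library labelled RNAi-Ctrl 3 and 1718 FPKM in that labelled RNAi-GLAD 3. CG32641 (X, 13184478 to 13184996) was at 32.2, 34.0 and 30.3 FPKM in RNAi-Ctrl 1, RNAi-Ctrl 2 and RNAi-GLAD 3, and was listed at 0 in RNAi-Ctrl 3, RNAi-GLAD 1 and RNAi-GLAD 2. In the same way sordd2 (X, 15796908 to 15799162) was at 27.5, 29.1 and 25.7 FPKM in the former libraries and listed at 0 in the latter. Without both libraries numbered 3, an alternative added after the values were seen, limma called 527 of 9661 genes, 396 higher and 131 lower in RNAi-GLAD (2 libraries per group), and 2409 genes had an unadjusted p under 0.05. Without both libraries numbered 1 or both numbered 2 it called 0, with 208 and 53 genes at an unadjusted p under 0.05. Of the 527 genes, 522 (99.1%) had the opposite sign between the libraries labelled RNAi-GLAD 3 and RNAi-Ctrl 3. Every direction given for these 4 libraries thus rests on the labels of the libraries numbered 1 and 2. For 522 of the 527 called genes it goes against those of the libraries numbered 3. An exception is mt:ATPase6, called lower in RNAi-GLAD 1 and 2 (-0.35) and also lower in RNAi-GLAD 3 than in RNAi-Ctrl 3 (log2 difference -0.23). The mean level of the mitochondrially encoded genes was likewise lower in RNAi-GLAD 3 (4.65 log2 units) than in RNAi-Ctrl 3 (5.35).

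**Figure D2:**
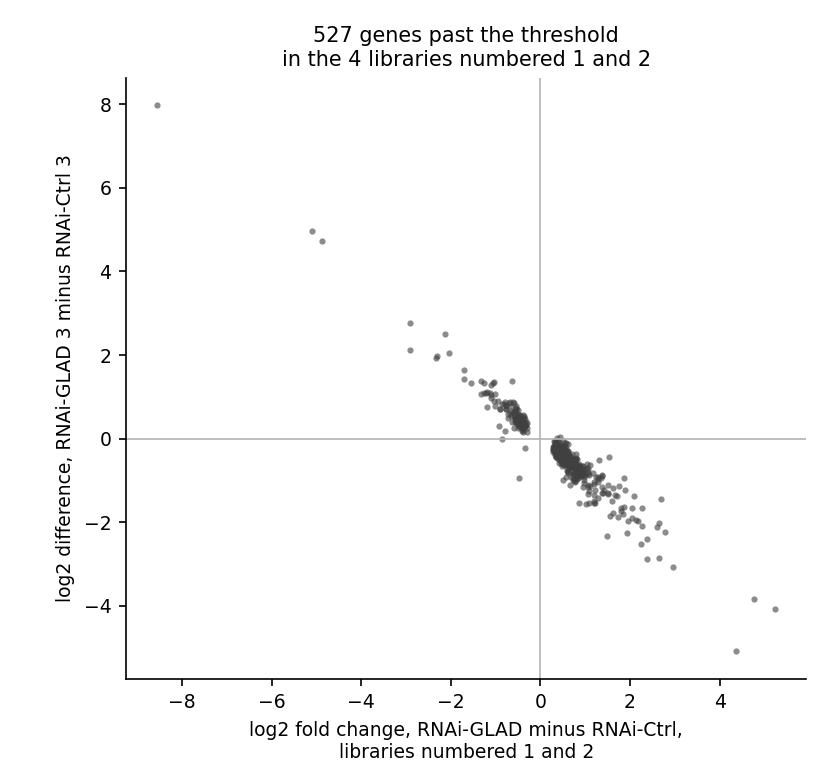
Log2 fold change between RNAi-GLAD and RNAi-Ctrl in the libraries numbered 1 and 2 (x axis) against the log2 difference between RNAi-GLAD 3 and RNAi-Ctrl 3 (y axis), 1 point for each of the 527 genes called in the former. Of these, 522 points lie in the quadrants of opposite sign, and Pearson's r across genes, which are not independent replicates, is -0.971.

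In the 4 libraries numbered 1 and 2, detoxification enzymes stood among the genes with the largest differences. GstD2 (3R, 12371971 to 12372704), a glutathione S-transferase that conjugates foreign compounds, rose from 5.82 ± 0.402 to 184 ± 18.2 FPKM (SD, n = 2 each), a log2 fold change of 4.76 ± 0.09 (SE, adjusted p = 0.00122). Its neighbours GstD5 (2.65), GstD1 (1.42) and GstD3 (0.95) rose too, and with Trxr1 (0.37) and Sod1 (0.41) made 6 of the 34 glutathione S-transferase and antioxidant genes called, all higher; adjusted over the list alone, 11 were higher and 1 lower. The list passed (adjusted p = 0.0294; adjusted p = 0.807 with an estimated correlation; 0.0284 with fry), and it did not without RNAi-GLAD 2 (adjusted p = 0.139). Cytochrome P450 genes went both ways, with 8 of 58 higher and 4 lower (10 and 10 adjusted over the list alone), and the list did not pass (adjusted p = 0.225; its mean fold change was positive, 0.02, and its median negative, -0.10). Cyp4e3 rose from 13.05 ± 1.33 to 95.4 ± 0.0111 FPKM, and Cyp4s3 (2.05), Cyp6a14 (1.51) and Cyp6a2 (1.29) were higher, while Cyp12d1-d (-2.33) was lower. GstD genes, Cyp12d1-d, Amy-p and CG32641 have close copies beside them, and how reads of such copies were divided is not given in the sources used here.

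Many genes of protein folding in the ER rose in RNAi-GLAD 1 and 2. Of 21 tested members, 12 were higher, 1 was lower and 8 did not pass (15 and 1 adjusted over the list alone; adjusted p = 2.29e-07 for the list, 0.807 with an estimated correlation and 0.0744 with fry). Sil1, an exchange factor of the ER chaperone BiP, rose from 7.36 ± 1.69 to 51.0 ± 11.1 FPKM (log2 fold change 2.64 ± 0.21), and CaBP1, a protein disulfide isomerase, from 33.1 ± 4.87 to 162 ± 24.1 FPKM (2.26 ± 0.15). Ero1L (1.10 ± 0.07), the oxidase that drives disulfide formation, and ERp60 (0.87 ± 0.06) were higher as well, and the lower member was prtp (-0.39 ± 0.04). The aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 11 of 33 cases with 0 lower (13 adjusted over the list alone; adjusted p = 2.66e-06, or 0.807 with an estimated correlation and 0.0284 with fry); ValRS (0.92), AspRS (0.88), AlaRS (0.64) and SerRS (0.53) had the smallest p. All 31 proteasome genes had positive fold changes with a median of 0.21; only Prosbeta7 (0.44) passed over all genes and 24 passed adjusted over the list alone (adjusted p = 9.44e-09, or 0.807 with an estimated correlation and 0.140 with fry). The calls of these 3 lists held without each of the 4 libraries in turn.

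**Figure D3:**
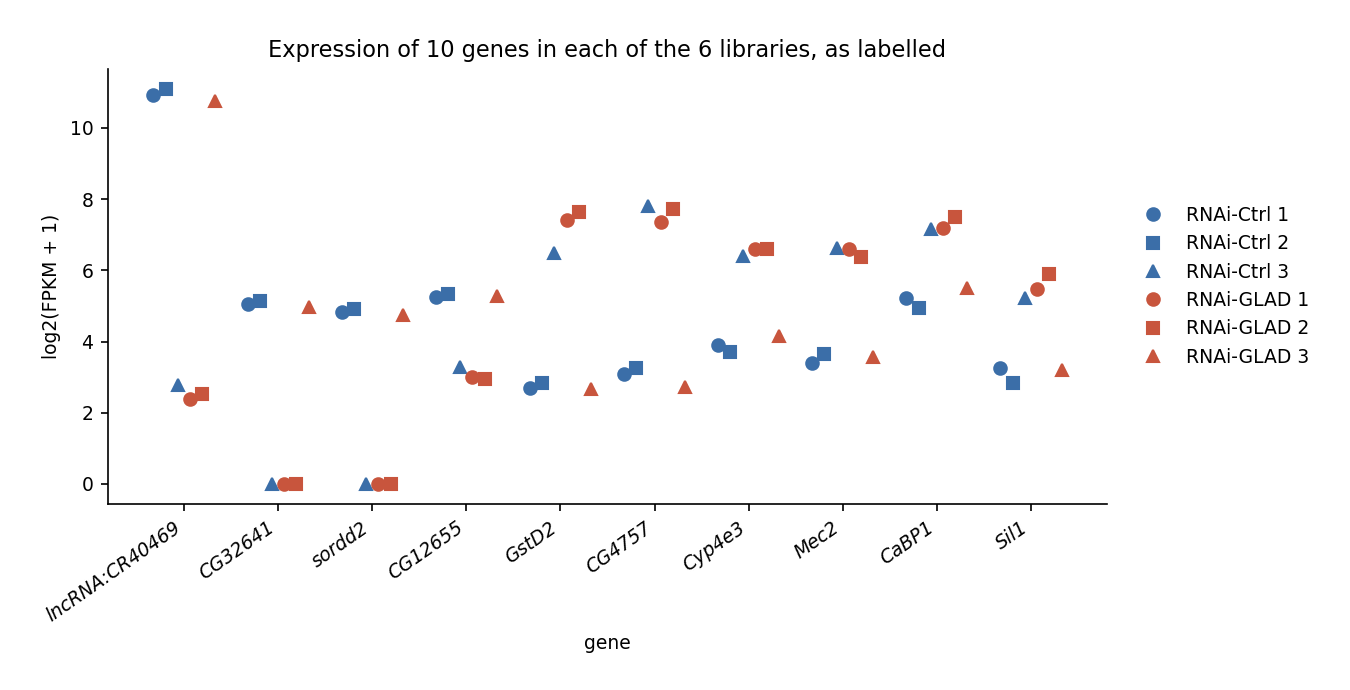
Expression as log2(FPKM + 1) (y axis) of 10 genes in each library (colour for the labelled group, symbol for the replicate number; 1 point per library). In every gene shown RNAi-Ctrl 3 lies with RNAi-GLAD 1 and 2 and RNAi-GLAD 3 with RNAi-Ctrl 1 and 2; for GstD2 the former are at 89.3, 171 and 197 FPKM and the latter at 5.37, 5.53 and 6.10 FPKM.

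Immune genes were also among the higher calls in these 4 libraries. Of 23 peptidoglycan recognition and NF-kB regulators, 7 rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00976, or 0.807 with an estimated correlation, 0.0744 with fry and 0.109 without RNAi-GLAD 2). They included Rel (0.81 ± 0.05), the NF-kB factor of the Imd pathway, pirk (1.08 ± 0.09), an inhibitor of that pathway, and the receptors PGRP-SA (0.84 ± 0.05) and PGRP-SD (1.74 ± 0.23). Of the antimicrobial peptides and Bomanins, 2 of 24 rose, Drsl4 (1.19) and Drsl5 (0.81), and adjusted over the list alone 4 rose and 1 fell. By sign 14 were positive and 10 negative. Among the negative ones were CecA2 (-2.71) and CecA1 (-2.09), which limma did not call over all genes (adjusted p = 0.0728 and 0.182). The list did not pass (adjusted p = 0.654; its median was 0.15 and its mean -0.13) and rested on single libraries, passing as higher without RNAi-GLAD 1 (adjusted p = 0.00509) and lying lower without RNAi-GLAD 2 (adjusted p = 0.0744). TotA, a stress-induced secreted peptide, rose from 288 ± 2.69 to 604 ± 4.92 FPKM, the only call of 9 Turandot and JAK-STAT genes (adjusted p = 0.222 for the list). Of 20 mitochondrial stress and ATF4 target genes, Gadd45 (1.51) and GstD1 were higher and P5cr-2 (-1.25) was lower (adjusted p = 0.232). Of 12 cytosolic heat shock genes, 0 passed (adjusted p = 0.435). The engulfment receptor drpr (0.68) was the only one of 24 glial genes called, while 17 of them had negative fold changes (adjusted p = 0.166). The adaptor ref(2)P (0.62) was the only one of 23 autophagy genes called (18 positive, adjusted p = 0.184). Of 19 fat body and yolk protein genes, fit (2.25) and Apoltp (0.80) rose and tsl (-0.52) fell. This list had 10 positive and 9 negative fold changes and did not pass (adjusted p = 0.937; its median was 0.03 and its mean -0.23). Amy-p (1.03), an amylase, and NimC4 (1.62), a phagocytic receptor, were each the only call of its own list, midgut and salivary digestion (adjusted p = 0.658) and hemocytes and clotting (adjusted p = 0.654). Outside the lists, CG8299 (5.25 ± 0.23), CG4757 (4.36 ± 0.14), Mec2 (2.97 ± 0.12), CG5246 (2.69 ± 0.33), Dgat2 (2.60 ± 0.06), which makes triglycerides, Srg3 (2.38 ± 0.08) and CG2444 (2.37 ± 0.11) completed the 12 higher genes with the largest fold changes.

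Some lists of neuronal, photoreceptor and energy metabolism genes passed on the lower side of RNAi-GLAD 1 and 2, by small amounts. All 17 pan-neuronal genes had negative fold changes (median -0.11, adjusted p = 9.02e-05), as had 21 of 25 synaptic vesicle genes (median -0.07, adjusted p = 0.00202), 25 of 32 phototransduction genes (median -0.09, adjusted p = 0.00922), 50 of 68 nuclear genes of oxidative phosphorylation (median -0.04, adjusted p = 0.00922) and 11 of 15 glycolysis genes (median -0.06, adjusted p = 0.0239). With an estimated correlation the adjusted p was 0.807 for each except oxidative phosphorylation, at 0.909. In these lists 0 members passed over all genes or adjusted over the list alone. With fry the adjusted p was 0.166 for the pan-neuronal list and 0.290 or higher for the others. Other neuronal lists did not pass: neuropeptides (16 of 28 positive, adjusted p = 0.760) and neurotransmitter synthesis and transport (8 of 18 positive, 0.680). Of the mitochondrial lists, the same held for mitochondrially encoded genes (2 of 11 positive, 0.129), mitochondrial ribosomal proteins (46 of 70 positive, 0.201) and mitochondrial dynamics (16 of 22 positive, 0.141). Their only called members were, in this order, mt:ATPase6 (-0.35), mRpL33 (0.69) and Phb2 (0.51). The neuronal gene slo, a potassium channel, was at 108 and 102 FPKM in RNAi-Ctrl 1 and 2 and at 86.0 and 90.3 FPKM in RNAi-GLAD 1 and 2. The pan-neuronal and synaptic calls held without each of the 4 libraries in turn, but phototransduction was lost without RNAi-Ctrl 2 or RNAi-GLAD 1 (adjusted p = 0.133 and 0.179), glycolysis without the same libraries (0.147 and 0.168) and oxidative phosphorylation without RNAi-Ctrl 1 or RNAi-GLAD 2 (0.195 and 0.386). Ribosomal protein genes moved apart: RpS21 (-0.95 ± 0.07) and RpL7A (-0.60 ± 0.06) fell, while RpL18 (0.76 ± 0.06) and RpS25 (0.67 ± 0.06) rose, among 79 members with 3 higher, 2 lower and no call for the list (adjusted p = 0.937). The hormone gene Ilp2 (-0.37 ± 0.05) was lower, and ChAT (0.53 ± 0.08), the enzyme that makes acetylcholine, was higher.

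The 12 lower genes with the largest fold changes in these 4 libraries were led by lncRNA:CR40469 (-8.56 ± 0.09, adjusted p = 4.35e-04), CG32641 (-5.09 ± 0.08) and sordd2 (-4.87 ± 0.08). CG8157 (-2.91 ± 0.16), CG15368 (-2.90 ± 0.20), Cyp12d1-d (-2.33 ± 0.23), CG12655 (-2.32 ± 0.06), topi (-1.71 ± 0.16), a regulator of transcription in the testis, and CG9547 (-1.70 ± 0.17) followed, with 3 transcripts outside the reference annotation. CG12655 was at 37.0 and 39.2 FPKM in RNAi-Ctrl 1 and 2 and at 7.04 and 6.65 FPKM in RNAi-GLAD 1 and 2. Markers of testis and accessory gland averaged 0.860 and 1.90 log2 units in RNAi-Ctrl 1 and 2 and 2.34 and 0.535 in RNAi-GLAD 1 and 2, so that libraries of the same group differed more than the group means. The number of calls rested on single libraries, at 1 gene without RNAi-Ctrl 1 or without RNAi-Ctrl 2 (lncRNA:CR40469 in both cases), 329 without RNAi-GLAD 1 and 149 without RNAi-GLAD 2. With 2 libraries per group chosen after the values were seen, the adjusted p-values describe these 4 libraries and not an independent repeat.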

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

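The alternatives for the 4 libraries numbered 1 and 2, the fits without both libraries of a number and voom were chosen after the data were seen; the others were set before. As labelled, the count of genes stayed at 0 under the other pseudocounts, filters, scalings, thresholds, trend, array weights (with 2270 genes at an unadjusted p under 0.05), voom and each library left out, and became 527 without both libraries numbered 3. The number of lists called, 10, ranged from 6 to 14 without each library, and was 0 with an estimated correlation and 0 with fry. Same-numbered libraries had correlations of deviations from the labelled group means of -0.354, -0.404 and -0.460, none of them positive, so the samples were treated as not paired. These values do not show that a pairing is absent, since the libraries numbered 3 stand with the other group, which alone can make them negative. The shares of genes compared between pairs of libraries below leave a pairing by number open. With the replicate block there were 0 genes and 13 lists as labelled, and 512 genes (380 shared) and 11 lists in the 4 libraries. There the count of 527 fell to 254 without a filter on low values, 165 without the mean-variance trend, 17 at the threshold of 0.01 and 104 with a log2 fold change of at least 1. It rose to 743 (493 shared) with a filter at a mean of 5 FPKM, lay between 458 and 540 under the other pseudocounts, scalings and array weights, and ranged from 1 to 329 without each library, which leaves a lone library in its group that is assumed to vary like the others. Quantile scaling called 328 higher and 176 lower genes (against 396 and 131), and voom called 493 genes, 431 of them shared. Of 30 lists not called, 13 as labelled and 9 in the 4 libraries passed without some library, 1 and 2 of them in both directions. Lists called in the 4 libraries numbered 0 with an estimated correlation and 2 with fry. No scaling moved the median of all genes by over 0.1 on the log2 scale. The genes given with a fold change in the Results, as far as they were run through the alternatives, kept its sign in each. Of 163 genes the naming rule chose as labelled, 3 turned without both libraries numbered 3: Hsp68 (-0.816 to 0.138), Hsp23 (-0.331 to 0.258) and Hsp83 (-0.196 to 0.189). In the 4 libraries 219 of the single-gene values under alternatives missed a threshold passed before, mostly without RNAi-Ctrl 1 or RNAi-Ctrl 2. The lowest correlation between libraries moved from 0.9603 to 0.948 with a pseudocount of 0.1 and no filter. Beyond fewer libraries or genes in a fit, the cause was not tested. Depth limits values below about 0.1 FPKM, which rest on few reads.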

Other observations

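All tests in this part were chosen after the results were seen.

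Several groups of transcripts were high in some libraries only, whatever the label. The yolk protein genes Yp1, Yp2 and Yp3, which the female fat body expresses, were at 296, 98.6 and 343 FPKM in RNAi-Ctrl 1, while Yp1 lay between 0.735 and 3.28 FPKM and Yp3 between 53.5 and 61.2 FPKM in the other 5 libraries. The heat shock genes Hsp26, Hsp27 and Hsp68 were at 121, 46.1 and 53.4 FPKM in RNAi-Ctrl 3, and Hsp26 lay between 6.67 and 13.2 FPKM elsewhere. Mst87F, a gene of sperm development, was at 10.6, 13.2 and 19.3 FPKM in RNAi-Ctrl 2, RNAi-Ctrl 3 and RNAi-GLAD 1 and between 0.566 and 1.03 FPKM in the other libraries. The digestive protease gene alphaTry ranged from 0.0516 FPKM in RNAi-GLAD 2 to 140 FPKM in RNAi-GLAD 1.

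Libraries correlated with r between 0.9603 and 0.987 over log2(FPKM + 1), on average 0.971 within and 0.9755 between groups. The first principal component held 42.0% of the variance and the next 31.2%. Neither separated the labelled groups, or RNAi-Ctrl 1, RNAi-Ctrl 2 and RNAi-GLAD 3 from the rest. RNAi-GLAD 1 and 2 lay at 29.2 and -5.11 on the first and at 11.6 and -28.9 on the next. The 3 against 3 split is among 10 possible, too few for a share under 0.05: as labelled 0 genes were called, a count that all 10 splits reach by construction, and the highest other count was 1303, for RNAi-Ctrl 1, RNAi-Ctrl 2 and RNAi-GLAD 3 against the rest. A count so far above the real one points to a structure of the samples that the labels do not follow. For gene lists, 6 of the 10 splits gave at least the 10 lists called as labelled, and the highest other split gave 18. Of the 3 splits of the 4 libraries numbered 1 and 2, the labelled one gave 527 genes and each of the other 2 gave 0. These 4 libraries were chosen after the values were seen, which favours the labelled split, and 3 splits are again too few for a share under 0.05.

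The libraries labelled RNAi-Ctrl 3 and RNAi-GLAD 3 stood with the other group: of the 527 genes called between the libraries numbered 1 and 2, 99.1% had the opposite sign between those numbered 3, RNAi-Ctrl 3 lay nearer the RNAi-GLAD 1 and 2 mean for 93.5% and RNAi-GLAD 3 nearer the RNAi-Ctrl 1 and 2 mean for 90.5%. A condition that moved both libraries numbered 3 alike would leave the sign of their difference as it was, and a condition that acted differently on each was not tested. RNAi-GLAD 1 and 2 stood together in the called genes, though their r over all tested genes was 0.963, near the lowest of any pair (0.9603). Their mean marker levels were the highest and the lowest of all 6 libraries (2.34 and 0.535 log2 units for testis and accessory gland, 2.72 and 0.550 for digestion). Of 9 pairs of a library of each side, at most 6 had the same order of marker level. This stands against RNA from testis, accessory gland or digestive tissue as the explanation for the called genes. A candidate explanation that these values leave open is an exchange of both libraries, at the level of flies, RNA, libraries or table columns, and an exchange of those numbered 1 and of those numbered 2 instead would give the same values, so the direction of the differences stays open too. Apart from RNA of these other tissues, no biological explanation was tested, since the labels name no other difference between replicates.

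Some clock genes, though not most of the list, moved together in both libraries numbered 3. The clock gene vri was at 31.0 and 36.7 FPKM there and at 9.88 to 15.7 FPKM in the other 4 libraries, tim at 34.5 and 43.9 against 20.8 to 23.9 FPKM, per at 15.6 and 19.8 against 9.48 to 10.3 FPKM, and to at 21.5 and 21.2 against 41.4 to 82.4 FPKM. Of 18 tested clock list members, 7 (38.9%) had both libraries numbered 3 above or both below the other 4, where chance gives 13.3%, and 15.8% of all tested genes did (Fisher's exact test, two-sided, p = 0.0154, for 1 of 15 pairs and a list singled out after its values were seen). Of these 7, Clk (14.77 and 14.61 against 14.83 to 16.43 FPKM) and dco (37.52 and 36.8 against 34.25 to 35.33 FPKM) lay outside by small amounts. Collection at another time of day may account for the 7 members, although RNAi-Ctrl 3 and RNAi-GLAD 1 also reached 7 members. For a batch that moves genes in general the 15.8% lies above chance but below 6 other pairs (up to 26.7%). These 6 pairs, RNAi-Ctrl 3 and RNAi-GLAD 1 among them, are those within RNAi-Ctrl 1, RNAi-Ctrl 2 and RNAi-GLAD 3 or within the rest. Libraries that stand together exceed other pairs for that reason alone, so neither comparison counts against a shared time of day or batch. Among pairs across these sides the libraries numbered 3 had the highest share, followed by RNAi-Ctrl 1 and RNAi-GLAD 1 (12.6%). RNAi-Ctrl 2 and RNAi-GLAD 2 came next (9.25%), and the other pairs across the sides had 7.52% or less. Same-numbered libraries thus had the highest shares, and a batch or pairing by replicate number stays open and was not tested. The labels give no time of collection, so a shared time of day and a batch cannot be told apart.

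X-linked genes were frequent among those lower in RNAi-GLAD 1 and 2: 38 of 120 lower genes with a known place (31.7%) were X-linked, against 16.5% of the tested genes (odds ratio 2.38, Fisher's exact test, two-sided, p = 3.28e-05), and 50 of 377 higher genes were (13.3%, odds ratio 0.766, p = 0.0889). The test counts genes as independent, which they are not, so its p-values do not measure the spread between flies or libraries. A change of dosage compensation across the whole X chromosome is argued against by median log2 fold changes of -0.016 for X-linked and 0.032 for autosomal genes, a difference of -0.048 where the lower genes have a median of -0.54. Another share of males would move the genes more active in females together, in the libraries that carry the X-linked difference. The difference of RNAi-GLAD 3 from RNAi-Ctrl 3 was 0.858 of that of RNAi-Ctrl 1 in the median X-linked lower gene (lower quartile 0.690). For Yp1, Yp2 and Yp3 it was only 0.00181, 0.0191 and 0.0201 of it. For fit it was 0.902, but opposite in direction to the X-linked lower genes. This gene was higher in RNAi-GLAD 1 and 2 (log2 fold change 2.25) and lower in RNAi-GLAD 3 than in RNAi-Ctrl 3 (-2.51). The yolk ratios divide by a difference from RNAi-Ctrl 1, the library with the high yolk values, so they cannot decide on another share of males. The yolk genes and fit did not move together, but another share of males stays open. A difference in X-chromosome background between the fly lines may account for the excess, and transcripts listed at 0 such as CG32641 and sordd2 are of the kind it could give. It was tested only by the excess among the lower genes itself, which cannot decide it, and the higher genes showed no excess. An effect of the GLAD construct stays open and was not tested.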
